A study of Mus musculus with 6 samples.

How the data were processed

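Gene expression was measured on 6 Affymetrix mouse gene arrays, 3 from Rb1+/+ and 3 from Rb1L/L mouse embryonic fibroblasts (MEFs), the mixed connective tissue cells that grow out of a minced embryo. Per the labels, the cultures came from embryos of day 13.5, were grown to passage 4, and gave total RNA while they were proliferating; the RNA was extracted with TRIzol and labelled with biotin. The deposited table holds log2 values made with RMA, and Partek is the second tool named, per the submitters' processing notes; their versions and settings are not given in the sources used here. RMA subtracts a background, forces all arrays onto one distribution and summarises the probes of each transcript cluster, so a change shared by most genes would be lost and folds of dim genes are compressed. The log2 values ran from 2.28 to 14.16, and the array medians over all clusters from 6.393 to 6.449. An array has no read depth, so the precision is limited by the number of arrays.

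Of the 35556 transcript clusters, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 were not named there. Clusters with 1 symbol were used, 21698 of them were found in the reference gene table (assembly GRCm38.p6), and they stood for 19938 genes; for the 999 genes with several clusters the brightest one was taken. A gene was tested when its mean over the 6 arrays lay above log2 5.081, the 90th percentile of 1194 olfactory and vomeronasal receptor genes, which left 15462 genes. The build behind the array annotation is not given in the sources used here, so no coordinates are printed, and the reference was used only for names and for which genes are neighbours.

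Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; log2 fold changes are Rb1L/L minus Rb1+/+ and are given with their moderated standard error (SE). The 3 cultures of a genotype are separate samples per the labels, and the limma p-values of single genes measure the spread between them. The replicate numbers pair the samples: the deviations of same-numbered arrays from their group means correlated at 0.30, 0.24 and 0.30 over all tested genes (0.12, 0.20 and 0.26 without the X and Y chromosomes), and the design text speaks of MEF pairs. The fit with the number as a block is therefore given beside list counts, list calls and shares that it changes, and the number of genes it calls with the other alternatives.

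Before the data were examined, 30 gene lists with 759 members were fixed, for the cell cycle and condensin, for stress and signalling pathways and for cell types an embryo culture can hold; 713 members were named on the array. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, a rotation test that asks whether the genes of a list move one way on balance without setting them against other genes. The named genes were also fixed then: per direction, the 10 genes with the largest change among those past the threshold whose groups did not overlap (predicted genes and small RNAs counted but not named), the up to 4 members of smallest p in each list, Rb1, the condensin II subunits, 5 sex-linked genes and the 6 divergent pairs with the smallest adjusted p.

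A divergent pair was defined as 2 tested protein-coding genes on opposite strands, head to head, with annotated starts at most 1000 bp apart. The reference table holds no strand, and the plan was to run this comparison only with one; the strand was instead taken from the cluster numbers, which on each chromosome ascend in 2 runs, the first read as the plus strand (99.2% of clusters lay in order). This was tested on 9 textbook bidirectional promoters, of which 8 could be placed and all 8 came out head to head, and on 57 genes named as opposite-strand transcripts, all of which fell in the other run from their partner. A strand was given to 14501 of 14643 tested protein-coding genes. Shares of changed genes were set against 10000 random gene lists matched on mean expression (two-sided permutation p), and correlations across pairs against 100000 re-pairings of partners.

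The procedure was tested on simulated data with the means and spreads of the 15462 genes. Of 100 genes changed 2-fold, 96% were recovered, and of 100 changed 1.5-fold, 84%, with 10 false calls; a list shifted as a whole was recovered with no other list called. For divergent pairs the permutation p of the share was 0.909 with nothing planted and 0.0002 with a planted change. Simulated genes were independent, which real genes are not. For single genes no change under 1.5-fold was planted, whereas in the data only 230 of the 1883 genes called changed 1.5-fold or more. Recovery of smaller changes was therefore not tested. Alternatives covered the block, moderation, array weights, normalization, filters, thresholds, distances and each array left out. Pairs of arrays left out, X and Y genes left out, a stricter criterion for divergent genes with and without the block, removal of list genes or of the largest pair, tail-to-tail pairs and 7 further gene lists were added after seeing the data. Pair tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.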

Results

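Transcript levels were compared between 3 Rb1+/+ and 3 Rb1L/L cultures of proliferating MEFs, 1 array per culture. Rb1 encodes the retinoblastoma protein pRb, which holds E2F transcription factors in check and binds chromatin proteins; the L allele is known to change the cleft through which pRb binds proteins with an LXCXE motif. The title of the series places the arrays in a study of condensin II, a chromosome-compacting complex, and of divergently paired genes, which share a promoter region and are transcribed away from each other. The 6 arrays correlated at 0.9948 to 0.996 within a genotype and at 0.9873 to 0.9927 between genotypes. The first principal component, with 54.2% of the variance, separated the genotypes, and the second, with 16.6%, placed arrays of the same number near each other.

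Rb1 itself measured log2 8.83 ± 0.19 (SD, n = 3) in Rb1+/+ and 8.93 ± 0.07 (SD, n = 3) in Rb1L/L cultures, a difference within the spread (limma adjusted p = 0.519). The altered allele is transcribed, so this level does not check the genotype labels. Xist, the RNA of the inactive X chromosome, was at log2 5.13 in Rb1+/+ replicate 1 and 4.79 in Rb1L/L replicate 1, and between 11.44 and 11.61 in the other 4 arrays. The Y-linked Eif2s3y stood at 8.36 and 8.47 in those same 2 cultures and at 3.63 or lower in the others, and Kdm5d and Uty were likewise highest there. Each genotype thus held 1 culture of male type and 2 of female type, and they carried the same replicate number. Ddx3y was not analysed here.

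The first comparison asked which genes differ between the genotypes. Interferon-induced genes had the largest increases in Rb1L/L cultures. Usp18, which restrains interferon signalling, was 13.8-fold higher (log2 fold change 3.79 ± 0.31 SE, adjusted p = 0.00146), Rtp4 was 11.9-fold higher (3.57 ± 0.28, adjusted p = 0.00146) and Ifit1, a sensor of foreign RNA, was 9.47-fold higher (3.24 ± 0.37, adjusted p = 0.00336). Oasl2, Bst2, Xaf1, Irf7, Sp100, Ccl5 and Phf11d followed, with rises from 3.05 down to 1.91 on the log2 scale. Irf7 is a transcription factor of the interferon response, Bst2 encodes tetherin, which holds virus particles at the cell surface, and Ccl5 encodes a chemokine.

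Decreases were smaller. Crct1, a gene of the epidermal differentiation complex, fell by 1.47 on the log2 scale (SE 0.18, adjusted p = 0.00431), and Tnfsf18, which encodes the ligand of the receptor GITR, fell by 1.27 (SE 0.17, adjusted p = 0.0051). Crabp2, which carries retinoic acid, and Edil3, a secreted matrix protein, had log2 fold changes of -1.11 (adjusted p = 0.0351, or 0.0676 with trended variances) and -1.04. The tight junction gene Cldn1 (-0.81), Mblac2, Serpinb6b, the histone gene H3c4 and the small heat shock gene Hspb8 (each -0.77) and Igfbp5 (-0.74) completed the 10 largest.

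**Figure D1:**
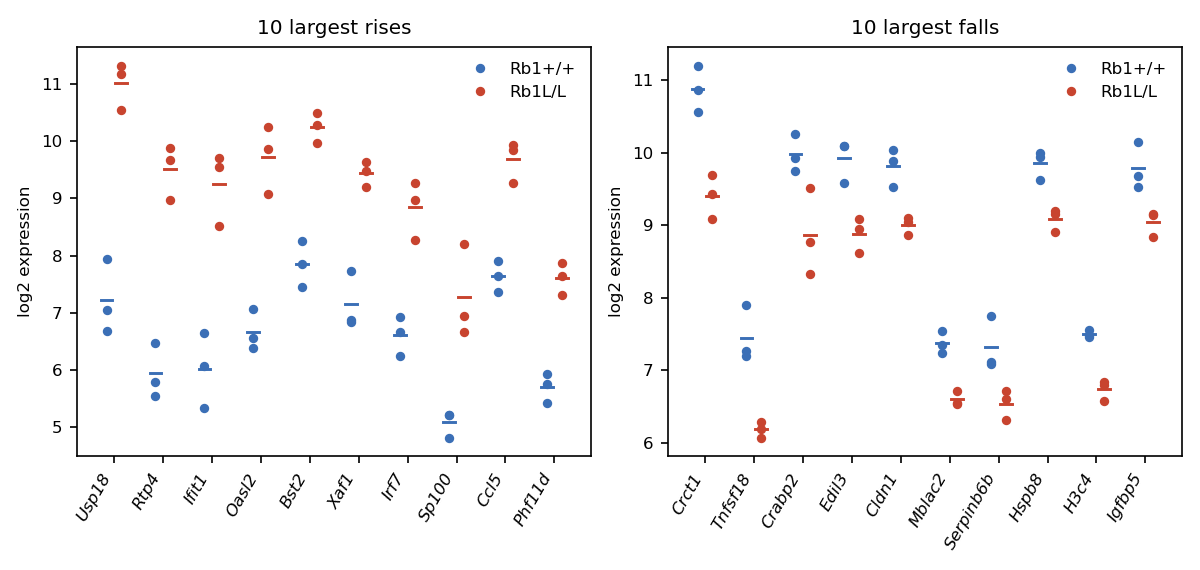
Log2 expression of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) in Rb1L/L cultures; each point is 1 array, blue for Rb1+/+ and red for Rb1L/L, and bars are means of 3. The genes were chosen among those whose genotypes do not overlap; Usp18 goes from a mean of 7.23 to 11.02 and Crct1 from 10.88 to 9.41.

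In all, 1883 of 15462 tested genes (12.2%) changed, 1098 higher and 785 lower; 54 of the former and 39 of the latter carry predicted or small-RNA names. At an unadjusted p under 0.05, 4444 genes (28.7%) differed. The groups did not overlap for any of the 1883, nor for 5337 genes (34.5%) in all, against 10% by chance. Most changes were small: 55 genes were more than 2-fold higher and 4 more than 2-fold lower. The split by direction depended on scaling, with 883 genes higher and 1067 lower after median centring and 1013 and 903 after quantile normalization. The count also rested on the number of arrays: it was 822 without Rb1+/+ replicate 1, 911 without Rb1+/+ replicate 3, 628, 622 and 1187 without Rb1L/L replicate 1, 2 and 3, and 92, 467 and 460 without both arrays numbered 1, 2 and 3. Of the named genes given here as changed, Crabp2, C1qa, Cx3cr1, E2f1, E2f6, Fdps, Ier2, Ncapg2, Rad21 and Tubb3 each lost the threshold in 5 of the 6 fits without 1 array.

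Among the lists fixed in advance, the interferon response list shifted most. Of its 29 tested members, 24 rose and none fell over all genes tested (28 and 0 adjusted over the list alone), and the median log2 fold change was 1.52. Besides Usp18, Rtp4 and Bst2, Dhx58, a cytosolic RNA sensor, rose by 1.53 ± 0.14 (SE; adjusted p = 0.00218). The members that did not pass, looked up after the result was seen, were Trim30a (1.38 ± 0.45 SE), Oas2 (0.47), Ifit2 (0.23), Oasl1 (0.21) and Rsad2 (0.07). With the replicate block 26 rose, Trim30a (adjusted p = 0.0357) and Ifit2 (adjusted p = 0.0457) included. The list passed camera (adjusted p = 2.96e-25) and fry (adjusted p = 0.0221), with adjusted p = 0.468 with an estimated correlation. Markers of macrophages and blood moved with it in part: 3 of 20 rose (Adgre1, 0.95 ± 0.20 SE; Cd14, 0.35; C1qa, 0.34, adjusted p = 0.0385, or 0.0576 with array weights) and Cx3cr1 fell by 0.34 (also 3 and 1 adjusted over the list alone), for a median of 0.18 (camera adjusted p = 0.0164; adjusted p = 0.62 with an estimated correlation). That call was lost without Rb1+/+ replicate 2 (adjusted p = 0.282), without Rb1L/L replicate 2 (adjusted p = 0.183) and without both, where the median was -0.034 (adjusted p = 0.941).

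Genes of S phase and mitosis formed the next groups. Of 42 E2F target and S phase genes, 30 rose and none fell (35 and 0 adjusted over the list alone, 31 and 0 with the replicate block), with a median log2 fold change of 0.40. Mcm6 (0.83 ± 0.08 SE, adjusted p = 0.00273) and Mcm7 (0.64 ± 0.06, adjusted p = 0.00273), subunits of the replicative helicase, rose with Dnmt1, the maintenance DNA methyltransferase (0.55 ± 0.06), and Rpa1, which coats single-stranded DNA (0.50 ± 0.05). Among the 12 that did not pass were Pcna (0.01 ± 0.07) and Ccna2 (-0.01 ± 0.08), chosen after their values were seen. Of 34 mitosis genes, 16 rose and none fell (23 and 0 adjusted over the list alone, 22 and 0 with the replicate block), with a median of 0.35; the spindle checkpoint gene Bub1b rose by 0.63 ± 0.08, the kinesin gene Kif2c by 0.64 ± 0.08, the centromeric histone gene Cenpa by 0.77 ± 0.12 and the centrosomal kinase gene Nek2 by 0.64 ± 0.10 (SE; adjusted p = 0.00428 to 0.00865). Camera gave adjusted p = 3.47e-20 and 6.05e-14 for the lists, and fry 0.0221 and 0.078; with an estimated correlation both had adjusted p = 0.468. E2f1 (0.25; adjusted p = 0.038, or 0.0529 after median centring) and E2f6 (0.35) rose among the 20 pocket protein, E2F and MuvB genes, of which none fell (4 and 0 adjusted over the list alone, 3 and 0 with the replicate block; camera adjusted p = 0.0164, or 0.127 without Rb1+/+ replicate 1; adjusted p = 0.468 with an estimated correlation), and Mybl2 (0.26) passed with the replicate block alone (adjusted p = 0.0293). Rbl1, E2f1, E2f2 and Mybl2 of this list also belong to the E2F target and S phase list.

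**Figure D2:**
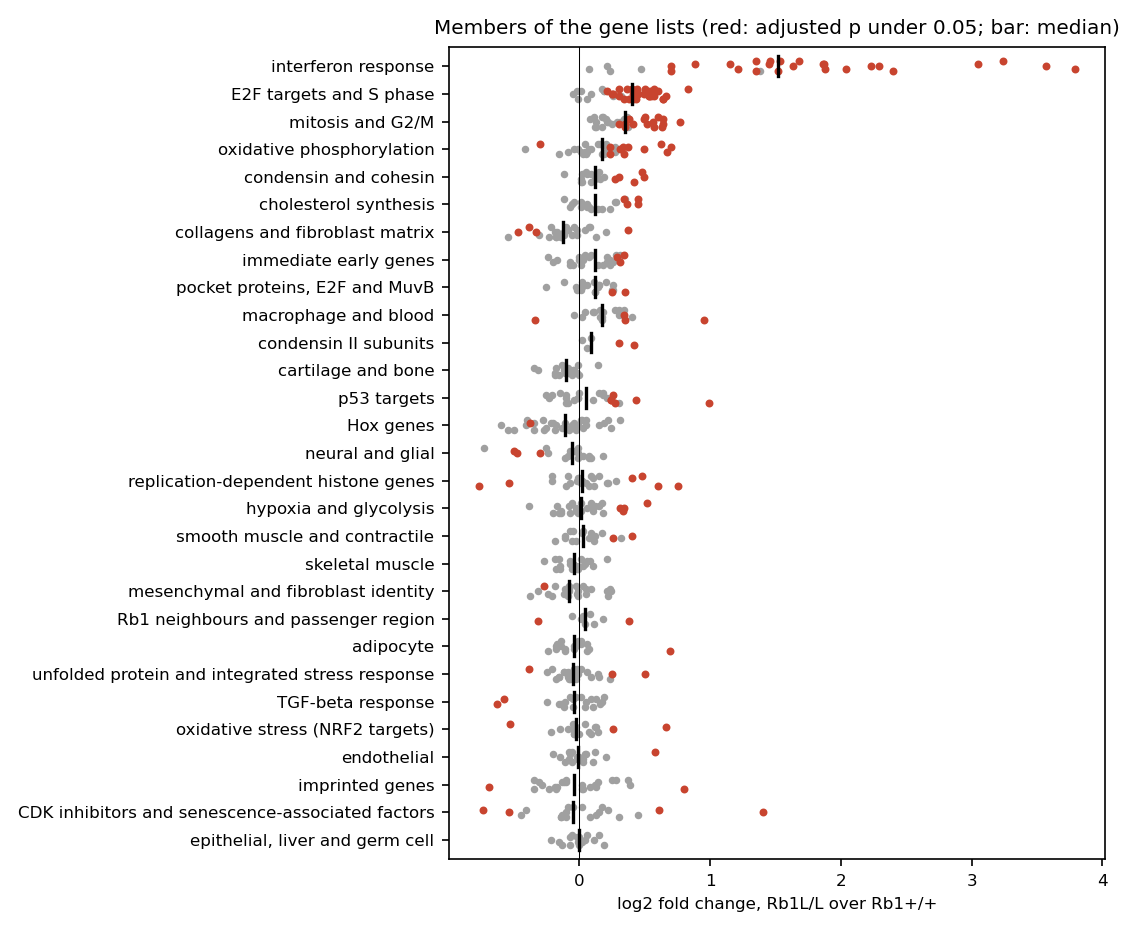
Log2 fold change (Rb1L/L over Rb1+/+, horizontal axis) of every tested member of the 29 gene lists, 1 point per gene, red where the limma adjusted p was under 0.05; black bars are list medians. The interferon response list has its median at 1.52, the E2F and mitosis lists lie at 0.40 and 0.35, and the other medians lie between -0.127 and 0.176.

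Condensin and cohesin genes shifted slightly upward, 5 of 19 having risen and none fallen (the same counts adjusted over the list alone; median 0.12; camera adjusted p = 0.0019, or 0.0537 without both arrays numbered 1; adjusted p = 0.595 with an estimated correlation). Ncapd2 and Ncapg of condensin I rose by 0.49 and 0.48, and the cohesin gene Rad21 by 0.27. Whether the shift of this list was separate from the rise of S phase and mitosis genes was not tested. Of the condensin II subunits, Ncaph2 rose by 0.30 ± 0.05 (SE; adjusted p = 0.0145) and Ncapg2 by 0.42 ± 0.11 (adjusted p = 0.038, or 0.0598 after quantile normalization). Ncapd3 (0.06 ± 0.05), Smc4 (0.09 ± 0.09) and Smc2 (0.02 ± 0.09, 0.00 after median centring) did not pass. The 5 subunits as a list missed the threshold (camera adjusted p = 0.06) and passed with the replicate block (adjusted p = 0.0469; adjusted p = 0.579 with an estimated correlation, fry adjusted p = 0.117). They also passed without Rb1+/+ replicate 2 (adjusted p = 0.0301), Rb1+/+ replicate 3 (0.0498) or Rb1L/L replicate 1 (0.0464).

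Of 33 oxidative phosphorylation genes, 10 rose and 1 fell (15 and 2 adjusted over the list alone, 10 and 2 with the replicate block; median 0.17; camera adjusted p = 1.99e-05, fry 0.0313; adjusted p = 0.468 with an estimated correlation), led by Ndufa4 (0.70 ± 0.08 SE) and Cox4i1 (0.62 ± 0.08). The gene that fell was Cyc1 (-0.30), named after its value was seen. The cholesterol synthesis genes Ebp (0.45), Pmvk (0.45), Fdps (0.34) and Idi1 (0.36) rose among 20, of which none fell (8 and 0 adjusted over the list alone, 6 and 0 with the replicate block; camera adjusted p = 0.00282; adjusted p = 0.595 with an estimated correlation), a call that did not hold without Rb1L/L replicate 3 (adjusted p = 0.0992, median 0.015). Of 26 immediate early genes, Dusp6 (0.34), Ier5 (0.29) and Ier2 (0.31; adjusted p = 0.0394, or 0.061 after median centring) rose and none fell (8 and 1 adjusted over the list alone, 5 and 0 with the replicate block; camera adjusted p = 0.0141, or 0.0667 without Rb1+/+ replicate 1; adjusted p = 0.468 with an estimated correlation). Collagens and fibroblast matrix genes shifted downward: Col3a1 (-0.33), Col11a1 (-0.47) and Lum (-0.39) fell, Fbln1 (0.37) rose and 28 of 32 did not pass (1 rose and 4 fell adjusted over the list alone, 1 and 6 with the replicate block; camera adjusted p = 0.00812, fry 0.0427; adjusted p = 0.468 with an estimated correlation).

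The other 18 lists did not pass camera. The Hox genes (median -0.108, adjusted p = 0.0818), of which Hoxb9 fell by 0.38 (6 genes fell with the replicate block), passed with the replicate block (adjusted p = 0.0373; adjusted p = 0.688 with an estimated correlation) and without Rb1+/+ replicate 3 (0.0087) or Rb1L/L replicate 3 (0.0293). The p53 targets passed without Rb1+/+ replicate 1 (adjusted p = 0.0435) or Rb1L/L replicate 2 (0.02), and the neural and glial list without Rb1+/+ replicate 3 (0.0229). With an estimated correlation over all arrays they had adjusted p = 0.595 and adjusted p = 0.468. Single members stood out. Mmp3, a matrix-degrading enzyme, rose 2.64-fold and the CDK inhibitor gene Cdkn2d by 0.61, while Igfbp3 had a change of -0.54. Tap1, a peptide transporter of antigen presentation, rose by 0.99 and led the 6 of 24 p53 target genes that rose, with Tnfrsf10b at 0.43. Among imprinted genes Nnat rose by 0.80 and Peg10 fell by 0.69, and Tgfb2 and Tgfbi fell by 0.63 and 0.58. Lpl (0.69), the endothelial receptor gene Kdr (0.58) and the stress enzyme gene Nqo1 (0.66) rose, and the neural genes Fabp7, Tubb3 and Ncam1 fell by 0.50, 0.48 and 0.30. Of the 19 tested genes of the oxidative stress (NRF2 target) list, which holds Nqo1, 2 rose and 1 fell. Histone genes went both ways, H2ac4 up by 0.75 and H2bc4 down (-0.54). No member of the cartilage and bone, skeletal muscle, or epithelial, liver and germ cell lists passed, although fry called the cartilage and bone list as a whole (median -0.102, adjusted p = 0.0354). With the replicate block, 7 p53 targets rose and 1 fell, 3 imprinted genes rose and 5 fell (1 and 1 without it), 3 CDK inhibitor and senescence genes rose and 4 fell (2 and 2), and 2 mesenchymal genes fell (1). For the NRF2, endothelial, and CDK inhibitor and senescence lists, the median was below 0 while the mean and the direction of camera were above it. With the replicate block, fry called none of the 29 lists (smallest adjusted p = 0.0624; 10 at an unadjusted p under 0.05), against 5 without it.

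The second comparison concerned divergently paired genes. Among 880 such pairs, Psme2, a proteasome activator subunit, and Rnf31, a ubiquitin ligase, rose together by 1.19 ± 0.06 and 0.44 ± 0.08 (SE; adjusted p = 0.000262 and 0.0142), as did Dtx3l and Parp9, partners in a ubiquitin ligase complex, by 1.27 ± 0.14 and 1.64 ± 0.15 (adjusted p = 0.00295 and 0.00231). In 4 further pairs 1 gene passed. Tap1 rose by 0.99 beside Psmb9 at 0.25 (adjusted p = 0.124), Mcm7 by 0.64 beside Ap4m1 at 0.29 (adjusted p = 0.083, or 0.0247 with the replicate block), Rpa1 by 0.50 beside Smyd4 at 0.21 (adjusted p = 0.114) and Cdca5, a cohesion factor, by 0.80 beside Zfpl1 at 0.00 (adjusted p = 0.978). Both partners passed in 27 pairs, of which 13 rose together, 6 fell together and 8 went opposite ways, and 1 partner passed in 240 pairs.

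Of the 1760 paired genes, 608 (34.5%) had an unadjusted p under 0.05, against a median of 32.9% (central range 30.9% to 34.9%) in expression-matched random lists (permutation p = 0.109, two-sided). The share passed without Rb1+/+ replicate 1 (permutation p = 0.0134), Rb1L/L replicate 1 (0.0444) or Rb1L/L replicate 3 (0.0354). At the adjusted threshold, a criterion added after seeing the data, 294 genes (16.7%; 203 higher and 91 lower) passed against 14.5% (13.0% to 16.0%) in random lists (permutation p = 0.0036). With the replicate block neither share differed from random lists by the test: 36.1% at the unadjusted threshold (permutation p = 0.763) and 17.6% against 17.0% at the adjusted one (permutation p = 0.468). Across pairs, which are not independent replicates, the partners' log2 fold changes correlated with Pearson r = 0.177 and Spearman rho = 0.133 (permutation p = 1e-05, the smallest the re-pairings can give, and 7e-05). Without Dtx3l and Parp9 r was 0.13 (permutation p = 9e-05). Adjacent genes on the same strand correlated at 0.089 over 6963 pairs, and the difference from the divergent pairs was within the range of 880 randomly drawn same-strand pairs (0.001 to 0.221, p = 0.17 from 10000 draws). For 826 tail-to-tail pairs r was -0.017 (permutation p = 0.629). Of the 9 other ways to part the 6 arrays into 3 and 3, each of which keeps part of the genotype difference, 2 gave r of 0.177 and 0.182 and 7 gave 0.074 to 0.146.

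**Figure D3:**
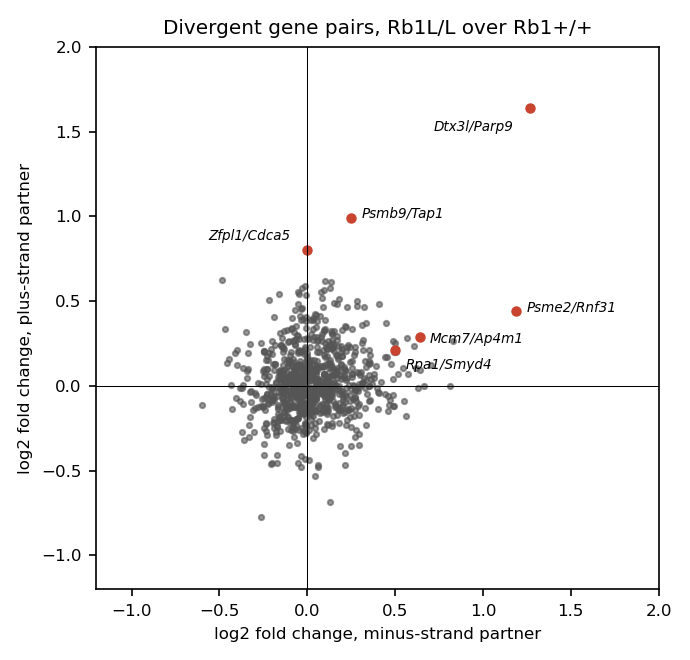
Log2 fold change (Rb1L/L over Rb1+/+) of the minus-strand partner (horizontal) and the plus-strand partner (vertical) for 880 divergent gene pairs, 1 point per pair, with the 6 pairs of smallest adjusted p in red. Dtx3l and Parp9 lie far from the rest at 1.27 and 1.64, and the correlation over all pairs is 0.177.

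The third comparison covered the neighbours of Rb1, since a targeted allele can carry linked variants of another strain. Within 20 Mb of Rb1 on its chromosome, 42 of 249 tested genes changed, 30 higher and 12 lower. Psme2 (1.19), Phf11d (1.91) and Irf9 (1.45) were among those that rose (Irf9 chosen after its value was seen), and of the genes next to Rb1, Med4 rose by 0.38 and Esd fell by 0.32 (adjusted p = 0.0129, or 0.0547 with the mean of its clusters) while Rcbtb2 (0.18) and Lpar6 (0.11) did not pass. An unadjusted p under 0.05 was found for 34.1% of the neighbours, against 28.5% (23.3% to 33.7%) in matched random lists (permutation p = 0.0414). The share did not pass with the replicate block (36.1%, permutation p = 0.0944), or within 10 Mb (33.3%, permutation p = 0.277), while over the whole chromosome it passed (33.8% of 533 genes, permutation p = 0.0108). It did not pass without Rb1+/+ replicate 1 (permutation p = 0.0632), Rb1+/+ replicate 3 (0.0758), Rb1L/L replicate 1 (0.071) or Rb1L/L replicate 2 (0.0808).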

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

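All tests in this part were chosen after the result was seen, except those on other small RNAs and on the 75th percentile of host genes, and the counts over other splits for divergent pairs and the neighbours of Rb1, which were written down before their values were known.

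Transcript clusters that the comparisons above left out also changed. Of 1011 clusters above the floor that carry several gene symbols, 167 changed by limma at the adjusted threshold (114 higher and 53 lower), and of 7121 with no gene named here, 44 changed (41 higher and 3 lower).

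The first pattern is the rise of the interferon genes. More macrophages or other blood cells in the Rb1L/L cultures are argued against: the 75th percentile of the 20 marker genes' log2 fold changes was 0.33, far under the interferon median of 1.52 and none of the 20 belongs to another list; a change within such cells stays open, Lyz2 standing at log2 10.52 in Rb1+/+ and 10.69 in Rb1L/L cultures. Linked variants acting directly on each changed gene of the interferon list are argued against, since 1 of these 24 lies within 20 Mb of Rb1. That gene is Irf9 (1.45), which could act on the others, so the count cannot decide whether a linked variant acted through it. This stays open. Phf11d (1.91) and Psme2 (1.19), which are not in the list, also rose within 20 Mb. A single pair of cultures is argued against, with medians of 1.14, 1.85 and 1.74 in numbers 1, 2 and 3. A response of the mutant cells themselves stays a hypothesis, and an infection or another outside source of interferon in 1 genotype's cultures was not tested.

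The second pattern is the rise of S phase and mitosis genes. An equal rise of all cycle genes is argued against. Of the 67 members above log2 8, 26.9% (18, 8 above and 10 below) had a 95% interval that excluded the common mean of 0.37. With an equal rise 5% would by chance. Ccne2 (-0.05), Ccna2 (-0.01) and Pcna (0.01) were lowest. A larger share of cycling cells need not raise all these genes alike, so the test cannot decide whether that share differed. A single pair is argued against, with medians of 0.47, 0.33 and 0.30 in the 3 numbers. A larger share of cycling cells, a shift between cycle phases and weaker repression by pRb all stay open as untested hypotheses, since the arrays measure no cell counts.

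The third pattern was noticed in the data: small nucleolar RNAs, which guide the modification of ribosomal RNA, were higher in Rb1L/L cultures (25 of 47 higher, none lower; median 0.46). Better recovery of all small RNAs was set against the 151 other small RNA genes, 137 of them microRNA genes. Their median was -0.07 and their 75th percentile 0.02, so as a set they did not rise. They were dimmer, at a median level of log2 6.65 against 8.43 for the small nucleolar RNAs. Only 89 lay above log2 6.452, the 99th percentile of the receptor genes, and folds of dim genes are compressed. The 14 that are not microRNA genes had a median of 0.17. The values thus argue against it for the microRNA genes at most, and better recovery of other small RNAs stays open. Higher host gene transcript levels as the whole cause are argued against for the 25 of 47 (53.2%) with a tested host. The 22 hosts had a median of 0.06 and a 75th percentile of 0.23, and these 25 a median of 0.33. Of the 25, 21 lay above their host (median difference 0.26, permutation p = 0.00024 from sign flips). That p measures the spread across small nucleolar RNAs, which share the 6 arrays and are not independent replicates, and not the spread between cultures. For the 22 with no tested host (median 0.54), higher host transcript levels cannot be told apart. Recovery of nucleolar RNA alone may differ between extractions, and no value above bears on it.

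The 6 arrays can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split gave 1883 changed genes and the other 9 none by limma at the adjusted threshold (263 to 910 at an unadjusted p under 0.05), so 1 split reached the real count. Each of the other 9 mixes the genotypes, so much of the genotype difference goes into the spread within its groups. Few calls could be foreseen there, and their absence is no reference for the 1883. For gene lists past camera the real split gave 10 and the highest other 13, with 3 splits reaching 10, so the number of lists past camera does not set the genotype split apart. The share of changed genes among divergent pairs differed from random lists by 1.7 percentage points, and by at most 1.3 in size in other splits (1 split). For the partner correlation the values were 0.177 and 0.182, with 2 splits reaching the real value at 4 decimals (0.1774) and 3 at 3 decimals, and for the neighbours of Rb1 a difference of 5.6 points against at most 2.0 in size (1 split). The differences for divergent pairs and for the neighbours count genes at an unadjusted p under 0.05. The genotype split had 4444 such genes and the others 263 to 910. Fewer such genes leave less room for a difference in points, so these differences do not set the genotype split apart. The other splits that part all 3 pairs, as the real one does, also called no gene, but they mix the genotypes too.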

How the results depend on the processing

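Alternatives named above as added were chosen after seeing the data. The count of 1883 changed genes stayed within 1.5 times under the block (2232, of which 1742 were shared), the random pair correlation, trended and robust variances, array weights, both normalizations, both filters, the mean of clusters and without X and Y genes. It was 67 with an ordinary linear model per gene, 3087 at adjusted p under 0.10, 803 with every cluster tested, 248 at unadjusted p under 0.05 and 1.5-fold, and 230 at adjusted p under 0.05 and 1.5-fold. Of these, 3 change the threshold itself. The ordinary model is the same fit without moderation, which borrows information on the spread from other genes. The count of 1883 thus rests on moderation. For every cluster the cause was not tested. Leaving out arrays gave 92 to 1441. With arrays or pairs left out, 8 to 13 lists passed camera; an estimated correlation left 0 (2 at an unadjusted p under 0.05) and fry 5. The share of changed divergent genes passed with quantile normalization (35.6%), the stricter filter (39.2%), starts within 2000 bp (34.5%) and unadjusted p under 0.01 (20.1%). It also passed in 3 of the 6 fits without 1 array and at the adjusted threshold (16.7%). At that threshold it passed without the members of the interferon, S phase and mitosis lists (16.2%). Psme2, Dtx3l, Parp9 and Cdca5 are in none of these lists and stayed in. Dependence on the interferon and cell cycle responses as a whole was therefore not tested. The share did not pass with the block at either threshold (36.1% and 17.6%). With arrays left out the share at the unadjusted threshold ranged from 23.7% to 33.4%. The count over all tested genes at that threshold fell too, from 4444 to between 3021 and 4240. Lower shares with fewer arrays are thus not particular to divergent genes. Why the test passed under some settings and not others was not tested. The partner correlation passed under every setting run, but its size varied. It was lower with starts within 500 bp (r = 0.116, permutation p = 0.00136) and within 2000 bp (r = 0.113, permutation p = 0.00109). The highest r was 0.196, without Rb1L/L replicate 1. The share among the neighbours of Rb1 no longer passed with the replicate block (36.1%, also without X and Y genes), the random pair correlation (36.1%), trended variances (33.3%), array weights (34.1%), median centring (34.5%), no filter (29.5%), the stricter filter (42.1%), the mean of clusters (32.9%) and 10 Mb (33.3%). With arrays left out it ranged from 23.3% to 33.3%, beside the lower counts over all tested genes given above. The cause of the lost calls was not tested. No called list or named gene past the threshold turned around, except that the macrophage and blood median was -0.034 without both arrays numbered 2; of 95 named genes past the threshold, 44 lost it in at least 1 of the 6 fits without an array and 79 in at least 1 of the 3 fits without both arrays of a number. Over the 11 other settings 10 lost it at least once: C1qa, Crabp2, Ddit4, E2f1, Esd, Higd1a, Ier2, Ncapg2, Pdia6 and Snai2. With the block Hoxa10, Ier3, Rian and Osr1 also passed. Genes near the floor of log2 5.081 have compressed folds.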

Other observations

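The 7 lists tested in this part and the genes named from them were chosen after seeing the data, and their camera p-values are adjusted over these 7 alone. Genes of MHC class I antigen presentation were higher in Rb1L/L cultures: 6 of 15 rose and none fell (median log2 fold change 0.26, camera adjusted p = 6.13e-07; adjusted p = 0.121 with an estimated correlation). Among those that rose, Psmb8 also belongs to the interferon response list and to the proteasome list, and Tap1 to the p53 target list. H2-Q4, a class I heavy chain, rose by 1.51 ± 0.08 (SE), the immunoproteasome subunit Psmb8 by 1.35 ± 0.21 and Tapbp, which loads peptides, by 0.94 ± 0.11, whereas B2m, the shared light chain, stood at 0.03 ± 0.07. Proteasome subunits (16 of 42 rose and none fell; median 0.17), mitochondrial ribosomal proteins (20 of 76 rose and 1 fell; 0.16) and cytosolic ribosomal proteins (16 of 60 rose and none fell; 0.16) also passed, with camera adjusted p of 8.3e-08, 1.66e-09 and 1.47e-07. With an estimated correlation the adjusted p was 0.121 for proteasome subunits and for mitochondrial ribosomal proteins and 0.178 for cytosolic ribosomal proteins.

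Of 20 genes of the cornified envelope, the protein shell of outer skin cells, 7 fell and none rose (median -0.30, camera adjusted p = 6.13e-07; adjusted p = 0.121 with an estimated correlation). Besides Crct1 they included Ivl (-0.72 ± 0.19 SE) and Sprr1a (-0.69 ± 0.17); the Lce1 genes among them are close copies of each other and their probes can share signal. Small nucleolar RNAs had a camera adjusted p of 2.15e-17 (adjusted p = 0.121 with an estimated correlation). Interferons, their receptors and sensors of foreign nucleic acid did not pass camera (median 0.02, or -0.01 after median centring; adjusted p = 0.145; adjusted p = 0.289 with an estimated correlation) but passed fry (adjusted p = 0.0464). The sensor genes Cgas (0.41) and Tlr3 (0.38) rose. So did Adar (0.69) and Irf3 (0.22), list members that encode neither an interferon nor a receptor or sensor. Ifnb1, which encodes interferon beta, lay between log2 4.19 and 4.56 on the 6 arrays, under the floor, and was not tested.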
